A study of Mus musculus with 3 samples.

How the data were processed

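Gene expression was measured on Affymetrix arrays, which read biotin-labelled RNA with probes grouped into probe sets, in 3 samples of sorted cells from mouse tumours. All 3 samples carried the genotype label Dicer1 +/- and came from the stroma gate, that is live cells that were negative both for PECAM1, a surface protein of endothelial cells, and for tdTomato, a red fluorescent protein. The sample titles number the samples 1, 2 and 3, and each description carries a different identifier. The labels do not state that the samples came from separate animals, so every SD measures only the spread between these samples. Sample 1 differed from the others in Xist and Y-linked genes, and between samples 2 and 3 the spread may be technical. Dicer1 +/+ stroma, which the series title sets against Dicer1 +/- stroma, was not analysed here, and no comparison of genotypes could be made.

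The authors deposited log2 intensities, 1 value per probe set and array. Per the submitters' processing notes Partek was among the tools, with no version or role given, and the background correction, normalization and summarization of probes into probe sets are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 2.00 to 13.18. The array medians were 5.35, 5.34 and 5.36 for samples 1 to 3. Exactly equal values in at least 1 pair of arrays occurred in 4938 of 31873 probe sets (15.5%), and all 3 values were equal in 708. Among genes above background on at least 1 array, those with a tie had a median SD of 0.060 and those without one a median SD of 0.178. A tie among 3 values lowers the SD by construction, and the origin of the ties was not tested. The SD of a gene with tied values may therefore understate its spread.

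GEO's platform annotation gave 1 gene symbol for 23094 of the probe sets, several for 1764 and none here for 7015. Only probe sets with 1 symbol were used. Of these, 22923 matched a gene identifier in the mouse RefSeq gene table of assembly GRCm38.p6, used for names and gene type alone, and no symbol needed updating. They named 22087 genes, of which 810 had more than 1 probe set, and a gene was then represented by the probe set with the highest mean. No coordinates are given, since no genome build was named for the array values.

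The deposited table has no detection calls. A gene was called detected when its log2 intensity on every array lay above the 95th percentile of 1438 probe sets of olfactory, vomeronasal and taste receptors on that array, genes not expected in tumour stroma. This background reference stood at 5.16, 5.11 and 5.20 for samples 1 to 3. It is a threshold of detection, and levels of different genes were not ranked against each other because probes differ in brightness. With arrays, the number of arrays limits the precision, and a value from 1 sample has no error of its own.

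Before the data were examined, 36 gene lists were written for cell types and pathways, together with the tests, the alternatives and the rule for named genes. They held 552 symbols, none in more than 1 list, of which 498 were measured under a single symbol and 54 were not analysed here. For the 34 lists with at least 5 measured members, the detected share was set against that of all other named genes with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the lists, with a threshold of 0.05. The other 2 lists (Y-linked genes and X-inactivation transcripts) were given as values.

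Variation between the 3 samples could not be tested gene by gene, since no sample was measured on more than 1 array. The range over the 3 samples was given, and genes with a range above 1 (2-fold) were counted among genes detected on at least 1 array. For each list, the median over members of the difference between a sample's value and the gene's mean over the 3 samples was taken, and the range of the 3 medians was placed among 10000 random lists of the same size matched on mean expression in 10 bins. A list above the 95th percentile was counted. This percentile describes these arrays: random lists hold unrelated genes, while a list of genes that cells express together is expected to move together wherever samples differ in any way. Across genes, Pearson and Spearman correlations described the agreement of the arrays, and genes are not independent replicates.

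The named genes were Dicer1 and Pecam1, the first 4 measured members of each list described, the 10 genes with the largest range (gene models without a name and the receptor genes left out), and the 3 members with the largest range in each list above the 95th percentile. Any gene named in the closing section outside this rule was chosen after its values were seen, and the 6 further lists used there were written after the main results were seen. Alternatives changed the detection level, the normalization, the summary of probe sets, the size threshold, the filter on dim probe sets and the random lists, and left out each sample in turn. Alternatives restricted to protein-coding genes and those for the correlations were chosen after seeing the data. Background correction and slide could not be varied from a table of processed values.

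The procedures were tested on simulated data made from the real gene means with noise of SD 0.1. With 13636 genes in the step for single genes, all 50 seeded changes of 1.5 and none of the 50 of 0.5 exceeded the range threshold of 1, and none of the 13436 unchanged genes did. In the step for list variation, all 40 lists shifted by 0.3 and 11 of 200 unshifted lists passed the 95th percentile. The median SD of a real gene over the 3 samples was 0.165, larger than the simulated noise. Under that noise an unchanged gene could hardly reach a range of 1. The counts for single genes and list variation therefore give no error rate for the real arrays. In the step for detected shares, all 40 lists with every member detected and 1 of 200 random lists were called. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.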

Results

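The series was set up to compare gene expression in the stroma of tumours that differ in Dicer1, the gene of the endonuclease that cuts microRNA precursors. The values analysed here describe 1 group, stroma of Dicer1 +/- tumours, in 3 samples. Total RNA was taken from live cells sorted as negative for PECAM1 and for tdTomato, so that endothelial cells and fluorescent tumour cells were meant to be left out. Each sample was measured on 1 array, and levels are log2 intensities as deposited. Of 20658 named genes outside the receptor genes used as background reference, 12508 (60.5%) were detected on all 3 arrays. By construction about 5% of the reference lies above its own 95th percentile on an array, and 60 of 1429 reference genes (4.20%) passed on all 3.

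Dicer1 was detected in every sample, at 8.10 in samples 1 and 2 and 8.08 in sample 3, with a mean of 8.09 ± 0.0073 (SD, n = 3). The values of samples 1 and 2 were identical, and this SD may therefore understate the spread. Other genes of the microRNA machinery were also present. Drosha, which makes the first cut in microRNA precursors, stood at 7.05 ± 0.24 (SD, n = 3), Xpo5, which exports them from the nucleus, at 7.58 ± 0.12 (SD, n = 3), and Ago2, which loads the mature microRNA, at 8.42 ± 0.18 (SD, n = 3), also with equal values in samples 1 and 2. Of 14 measured members of this list 13 were detected, all but Ago4. Over this list the sample medians differed by 0.03, a range at percentile 9.06 of random lists. These values carry no information on the effect of the Dicer1 genotype, since they come from 1 genotype, and the probe set was not known to lie inside the altered part of the gene.

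The question of which cell types the gate held was addressed through the detected share of marker lists. Markers of fibroblasts, macrophages, neutrophils and antigen-presenting cells were detected completely. All 20 fibroblast genes passed, among them Pdgfra at 8.54 ± 0.71, Dcn at 11.62 ± 0.41, Lum at 10.41 ± 0.46 and Col1a1 at 10.15 ± 0.33 (SD, n = 3 each), the last 3 encoding matrix proteins. All 24 further genes of the extracellular matrix passed as well. So did all 24 macrophage and monocyte genes, with Cd68 at 10.83 ± 0.045, Adgre1 at 9.04 ± 0.51 and Csf1r at 10.29 ± 0.28 (SD, n = 3 each), and all 15 neutrophil genes, with S100a8 at 12.44 ± 0.021 and S100a9 at 12.30 ± 0.044 (SD, n = 3 each). Among genes of dendritic cells and class II presentation 13 of 13 were detected, with H2-Aa at 11.11 ± 0.26 (SD, n = 3). Of the pericyte and smooth muscle genes 13 of 14 were detected, with Rgs5 at 10.01 ± 0.59 and Acta2 at 10.59 ± 0.58 (SD, n = 3 each). Of the T cell genes 13 of 14 were detected, with the receptor subunit Cd3e at 7.71 ± 1.09 (SD, n = 3).

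By Fisher's exact test against the 60.5% of other genes, two-sided, 19 of 34 lists had an excess of detected members and none a lack at an adjusted p of 0.05. The adjusted p was 0.00013 for macrophage and matrix genes, 0.00056 for fibroblast genes, 0.0044 for neutrophil genes, 0.0074 for dendritic genes and 0.0235 for T cell and pericyte genes. Members of a list are not independent of each other, and these p-values treat them as if they were. Besides these 7 lists and the microRNA machinery, the excess covered cell division, DNA replication, the interferon response, chemokines, hypoxia and glycolysis, dissociation stress, the unfolded protein response, imprinted genes, contractile genes, ribosomal proteins and oxidative phosphorylation. With protein-coding genes alone as background, an alternative chosen after seeing the data, 12 lists kept an adjusted p under the threshold. The lists that lost it were the microRNA machinery, pericyte, T cell and hypoxia lists (adjusted p = 0.085 each), chemokines (adjusted p = 0.081), imprinted genes (adjusted p = 0.084) and the unfolded protein response (adjusted p = 0.13), all by the exact test. Under the alternatives fixed in advance, the T cell call was lost with the 99th percentile as reference, where 21.4% of members were detected, a share below that of other genes (adjusted p = 0.345, exact test), and with the median of all probe sets as background (adjusted p = 0.0531, exact test). Hypoxia genes lost their call with the 99th percentile (adjusted p = 0.233, exact test), imprinted genes with the 90th (adjusted p = 0.0743, exact test), and the unfolded protein response with the 90th (adjusted p = 0.175, exact test) and with the mean over arrays (adjusted p = 0.0647, exact test). With the 99th percentile the epithelial and gland list had a lack, with 0% detected (adjusted p = 0.0172, exact test).

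**Figure D1:**
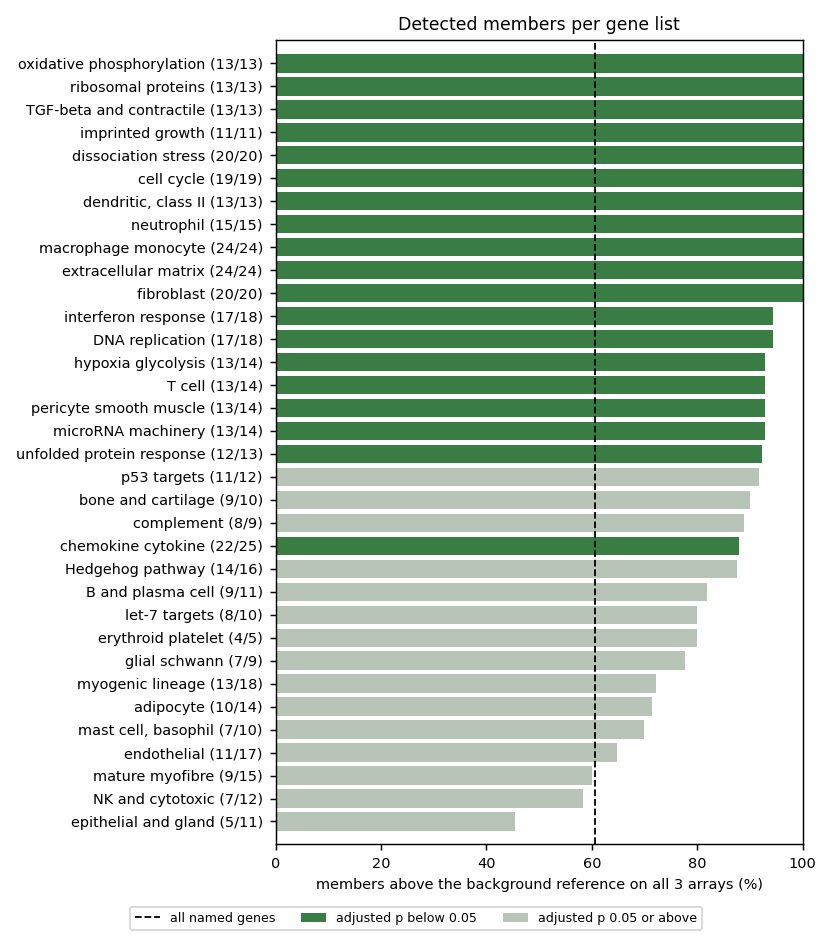
Horizontal bars give the percentage of each list's measured members above the background reference on all 3 arrays, with the counts in brackets, and the dashed line marks the 60.5% of all named genes. Bars of 19 lists are dark, which marks an adjusted p below 0.05 in Fisher's exact test, and the lowest share is that of epithelial and gland genes at 45.5%.

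In the main setting the other 15 lists, among them those for cells that the gate should leave out, were not called. Of 17 endothelial genes 11 were detected (64.7%, adjusted p = 0.86, exact test). Pecam1 itself was detected at 7.82 ± 0.55, Cdh5, the endothelial cadherin, at 6.91 ± 0.83, Kdr at 5.59 ± 0.45 and Tek at 5.67 ± 0.32 (SD, n = 3 each). Pecam1 is also made by leukocytes, whose markers were detected in the same samples. The gate should also leave out leukocytes with PECAM1 on their surface. The source of the Pecam1 signal was not tested, and endothelial cells that passed the gate stay open. Of 18 genes of the myogenic lineage 13 were detected (72.2%, adjusted p = 0.45, exact test), with the transcription factors Myod1 at 6.38 ± 0.070, Myog at 7.23 ± 0.24 and Myf5 at 7.09 ± 0.19 (SD, n = 3 each) and Myf6 not detected. Of 15 mature muscle fibre genes 9 were detected. Genes of the Hedgehog pathway reached 14 of 16 (adjusted p = 0.061, exact test), among them the pathway targets Gli1 at 6.60 ± 0.24, Ptch1 at 8.41 ± 0.60 and Hhip at 6.83 ± 0.50 (SD, n = 3 each). The remaining lists gave 9 of 11 B cell and plasma cell genes, 7 of 12 natural killer and cytotoxic genes, 7 of 10 mast cell and basophil genes, 10 of 14 adipocyte genes, 7 of 9 glial genes, 5 of 11 epithelial and gland genes, 4 of 5 erythroid and platelet genes, 9 of 10 osteoclast, bone and cartilage genes, 8 of 9 complement genes, 11 of 12 p53 targets and 8 of 10 let-7 targets, with adjusted p from 0.060 to 1.0 in the exact test. A probe set that failed detection is not shown to be absent from the cells. Short lists can also miss the threshold with nearly all members detected, as the bone and cartilage list did (adjusted p = 0.15, exact test). A list without a call therefore does not show that its cells were missing.

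The 3 samples were then compared with each other. Across the 13636 genes detected on at least 1 array, Pearson's r was 0.965 between samples 1 and 2, 0.960 between samples 1 and 3 and 0.956 between samples 2 and 3, and Spearman's rho was 0.964, 0.958 and 0.954. The median SD of a gene over the 3 samples was 0.165 on the log2 scale, and 777 genes (5.70%) had a range above 1. Of these 777, sample 2 was the highest in 323 and sample 3 the lowest in 360. Fewer genes passed when only 2 samples entered: 471 without sample 1, 373 without sample 2 and 248 without sample 3.

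The 10 genes with the largest ranges spanned 3.65 to 6.35 on the log2 scale. For most of them the lowest value lay below the background reference, so the exact size and order of these ranges carry little weight. Xist, the RNA that silences an X chromosome, was at 9.78 in sample 1 and at 3.43 and 3.49 in samples 2 and 3. The Y-linked genes Eif2s3y and Kdm5d were at 3.86 and 3.67 in sample 1, below the background reference, and at 7.03 or more in the others. Without sample 1 the ranges of Xist, Eif2s3y and Kdm5d were 0.065, 0.20 and 0.48, from 6.35, 4.85 and 3.83. Lipf, a secreted gastric and lingual lipase, was at 9.24 in sample 2 and at 3.11 and 3.42 in samples 1 and 3, and Bpifb1, a secreted protein of airway and oral glands, was at 9.36 in sample 2 against 3.92 and 4.92. Without sample 2 their ranges were 0.31 and 0.999, from 6.12 and 5.44. A pair of antibody kappa light chain segments, Igkv4-91 and another, were highest in sample 1, at 8.26 and 9.32, and lowest in sample 3, at 4.49 and 5.53. Their ranges of 3.77 and 3.79 were 2.26 and 2.17 without sample 1 and 1.51 and 1.62 without sample 3. Ifnb1, which encodes interferon beta, was at 7.48 in sample 2 and at 4.56 and 3.79 in samples 1 and 3, with a range of 0.77 without sample 2, from 3.69. Scarna10, a small RNA of the Cajal body, was at 9.0 in sample 1 and at 5.36 and 5.93 in the others, with a range of 0.57 without sample 1, from 3.65. Serpina1d, one of several near-identical protease inhibitor genes, was at 7.82 in sample 3 and at 3.70 and 4.63 in the others, with a range of 0.93 without sample 3, from 4.12. Light chain segments and Serpina1 copies share sequence with their neighbours, and their values may include signal from these.

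**Figure D2:**
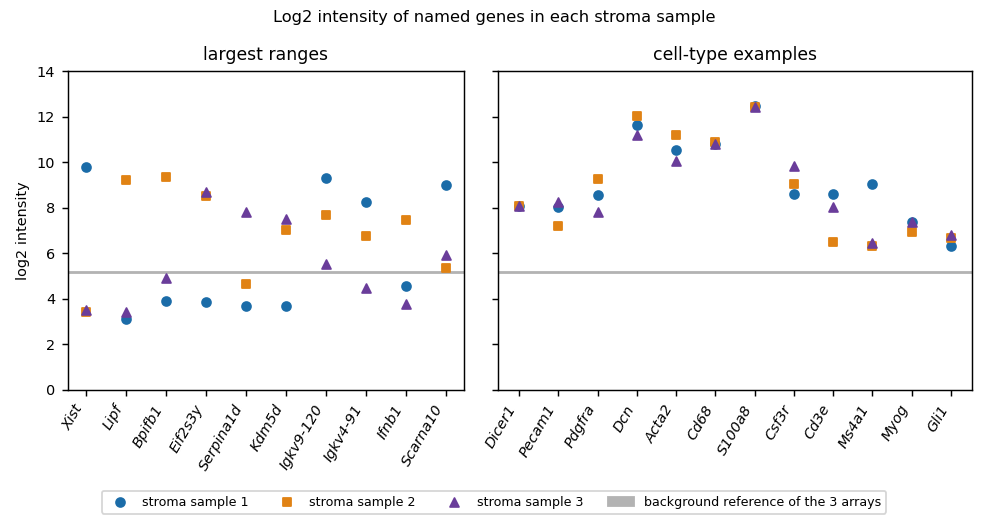
Points give the log2 intensity of the 10 genes with the largest range over the samples (left) and of 12 genes named as cell-type examples (right) in each of the 3 stroma samples, and the grey band spans the background references of the arrays, 5.11 to 5.20. Xist is above the band in sample 1 alone and Lipf in sample 2 alone, while Dicer1 and S100a8 nearly coincide in the 3 samples.

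Genes of fibroblasts, pericytes, matrix and complement were higher in sample 2 and lower in sample 3. Of 20 fibroblast genes, 19 were highest in sample 2 and 19 lowest in sample 3, with list medians of 0.076, 0.42 and -0.47 for samples 1 to 3, a 1.85-fold span. Pi16 and Cd34, markers of adventitial fibroblasts, were at 10.68 and 10.54 in sample 2 and at 8.94 and 8.58 in sample 3, and Pdgfra was at 9.24 and 7.82. Pericyte and smooth muscle genes spanned 2.15-fold, with 13 of 14 highest in sample 2, among them the contractile genes Myh11 (10.02 in sample 2 and 7.90 in sample 3), Cnn1 (8.92 and 7.16) and Tagln (9.87 and 8.37). Of 24 matrix genes 21 were highest in sample 2 and 22 lowest in sample 3, with Tnxb, Eln and Loxl1 at 9.09, 9.74 and 10.15 in sample 2 and at 7.18, 8.26 and 8.78 in sample 3. Complement genes spanned 2.05-fold and 7 of 9 were lowest in sample 3, such as C4b at 8.11 against 9.48 and 9.70 in samples 1 and 2, C1s1 at 8.33 against 9.52 and 9.78, and Cfb at 7.17 against 8.39 and 8.40. Genes of the TGF-beta and contractile list spanned 1.51-fold with 10 of 13 highest in sample 2, Myl9, Tpm2 and Itga11 at 10.58, 8.86 and 7.74 there. The fibroblast, matrix, pericyte and contractile spans exceeded all 10000 matched random lists and the complement span lay at percentile 99.99. Without sample 3 the spans were 0.36 for fibroblast, 0.30 for matrix, 0.74 for pericyte, 0.47 for contractile and 0.22 for complement genes on the log2 scale, from 0.89, 0.63, 1.10, 0.60 and 1.03. Without sample 2 they were 0.57, 0.29, 0.34, 0.080 and 0.87.

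Leukocyte lists differed between the samples in different directions. T cell genes spanned 2.59-fold, with 12 of 14 highest in sample 1 and 14 of 14 lowest in sample 2. The T cell receptor subunits Cd3d and Cd3g were at 8.06 and 8.42 in sample 1, 5.89 and 5.14 in sample 2, and 7.23 and 7.33 in sample 3, and Cd8b1, a chain of the cytotoxic T cell co-receptor, was at 7.80, 5.65 and 6.01. B cell and plasma cell genes spanned 2.38-fold and 11 of 11 were highest in sample 1, with Ms4a1, which encodes CD20, at 9.05 against 6.34 and 6.45, Jchain at 8.69 against 5.07 and 6.81, and Cr2 at 6.71 against 4.25 and 4.36. Without sample 1 the B cell span was 0.15 on the log2 scale, against 1.25 with it, and the T cell span was 0.79 against 1.38. Without sample 2 the T cell span was 0.55. Neutrophil genes spanned 1.81-fold, with 14 of 15 highest in sample 3 and 12 lowest in sample 1, and were spread over Csf3r (8.62, 9.04 and 9.83 in samples 1 to 3), Elane (9.33, 9.93 and 10.81) and Mpo (9.75, 10.56 and 10.99), while S100a8 and S100a9 had ranges of 0.039 and 0.089. S100a8 and S100a9 lay near the highest values of the arrays, 13.18, 13.06 and 13.10 for samples 1 to 3. Whether their signal was saturated was not tested. Without sample 1 or sample 3 the neutrophil span was 0.41 or 0.42, from 0.86. Genes of dendritic cells and class II presentation spanned 1.58-fold and 13 of 13 were lowest in sample 2, with Flt3, Cd209a and Itgax at 8.36, 9.06 and 8.72 in sample 3 and at 6.66, 7.41 and 7.09 in sample 2, and the span of 0.66 was 0.22 without sample 2 and 0.37 without sample 3. These 4 spans exceeded all 10000 matched random lists.

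Macrophage and monocyte genes as a list spanned 0.15 (percentile 96.55), or 0.26 with the mean of the members in place of the median, and the members went different ways. Cd163, a scavenger receptor, was at 6.27 in sample 3 and 8.68 in sample 2, and C1qa, a complement subunit, at 9.95 and 10.88, while Arg1 was highest there, at 7.12 against 5.96 and 5.48. Without sample 3 the list's span was 0.031. Mast cell and basophil genes spanned 0.54 on the log2 scale (percentile 99.91), with the mast cell proteases Mcpt4 and Cma1 at 9.55 and 7.80 in sample 2 and at 8.42 and 6.75 in sample 3, and Hdc, which makes histamine, at 10.94 in sample 3 against 9.61 and 10.15. Their span was 0.24 without sample 2, 0.26 without sample 3 and 0.28 with the mean of the members, where it lay at percentile 88.2. Natural killer and cytotoxic genes spanned 0.39 (percentile 99.42), with Gzma at 6.55 in sample 1 against 5.54 and 5.48, and Nkg7 highest in sample 3 at 8.96. Their span was 0.19 without sample 1 and 0.20 without sample 2.

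Medians of the endothelial, muscle and bone lists were highest in sample 3. Endothelial genes spanned 1.53-fold with 13 of 16 highest in sample 3, Cdh5 at 7.81 against 6.17 and 6.75 and Emcn at 6.37 against 4.77 and 4.49, and this span was 0.022 on the log2 scale without sample 3, from 0.61. Lyve1, which lymphatic endothelium and some macrophages express, went the other way, at 7.13 in sample 3 against 9.38 and 9.90. Myogenic lineage genes spanned 1.52-fold with 13 of 16 highest in sample 3, with Tnnt2 at 8.80 against 7.86 and 7.32, Ttn at 6.92 against 5.79 and 5.49, and Myh8 at 5.64 against 4.13 and 5.49. The factors Myod1 and Myog were equal in samples 1 and 3, at 6.42 and 7.37. Mature muscle fibre genes spanned 1.61-fold with 8 of 11 highest in sample 3, Acta1 at 9.39 against 8.27 and 8.01, Mb at 6.60 against 5.69 and 5.38, and Myh1 at 5.44 against 4.60 and 3.94. Without sample 3 the myogenic span was 0.29 and the fibre span 0.15, from 0.60 and 0.69, and without sample 2 the myogenic span was 0.36. Osteoclast, bone and cartilage genes spanned 1.81-fold with 8 of 10 lowest in sample 1 and 7 highest in sample 3: the cartilage matrix genes Acan and Col2a1 and the bone matrix gene Ibsp were at 8.10, 8.10 and 8.64 in sample 1 and at 9.94, 9.66 and 10.19 in sample 3. The osteoclast genes went other ways, with Acp5 at 8.17, 7.18 and 7.61 in samples 1 to 3 and Ctsk at 8.84, 8.95 and 8.16. Without sample 1 or sample 3 the span of this list was 0.49 or 0.42, from 0.86. These 4 spans exceeded all 10000 random lists. Hedgehog pathway genes spanned 0.34 (percentile 99.74). Ptch1 was at 7.75, 8.55 and 8.93 in samples 1 to 3, whereas the co-receptor genes Boc and Gas1 were highest in sample 2, at 8.08 and 8.15, and the span was 0.012 without sample 2 and 0.19 without sample 1.

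**Figure D3:**
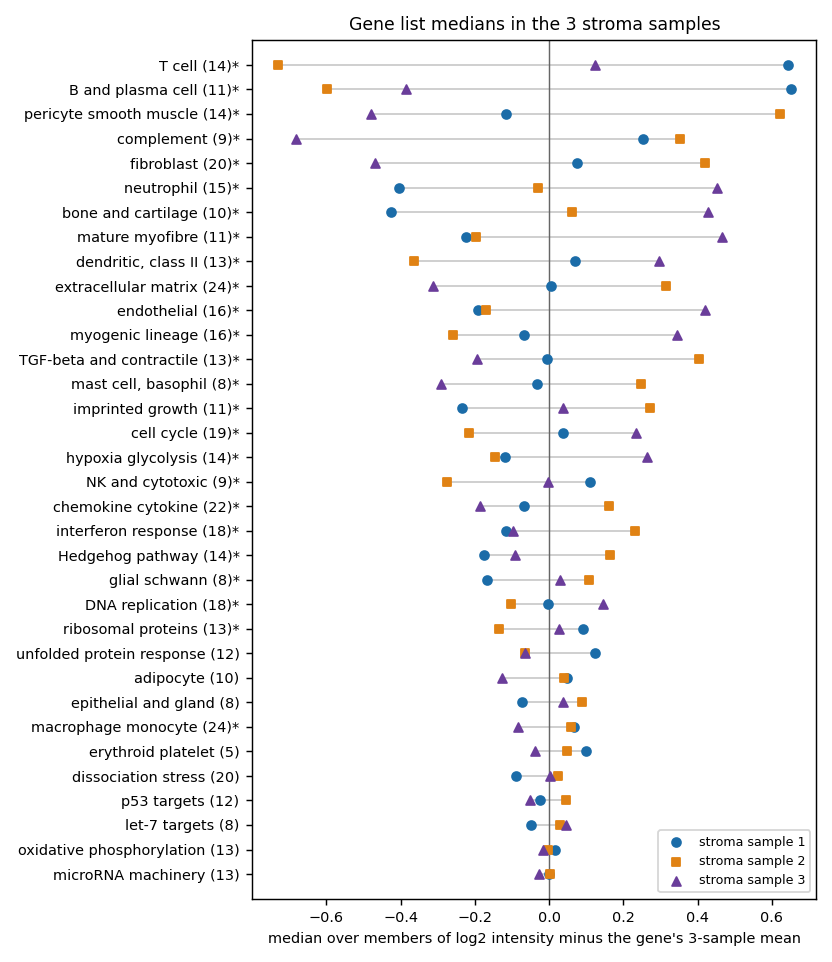
Points give, for each list and each of the 3 stroma samples, the median over members of log2 intensity minus the gene's mean over the 3 samples, with the number of members in brackets and an asterisk where the span exceeded the 95th percentile of 10000 matched random lists. Fibroblast and pericyte genes are highest in sample 2 and lowest in sample 3, T and B cell genes are highest in sample 1, and neutrophil genes are highest in sample 3.

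Of 34 lists, 25 lay above the 95th percentile of random lists, where chance alone gives 1.7 for lists of unrelated genes, and 18 to 22 did with 1 sample left out. Natural killer, B cell, glial and ribosomal genes no longer did without sample 1. Natural killer, mast cell, Hedgehog, glial, interferon, chemokine, contractile and ribosomal genes no longer did without sample 2, and macrophage, endothelial, muscle fibre, DNA replication and hypoxia genes no longer did without sample 3. With the mean of the members, mast cell, glial and ribosomal genes no longer did. Glial genes also fell below the 95th percentile with random lists not matched on expression (percentile 94.98) and with genes detected on all arrays (92.24). Cell division genes spanned 0.45 with 13 of 19 highest in sample 3, such as Plk1 and Cdc20 at 8.23 and 8.33 against 7.42 and 7.38 in sample 1, and Ttk was lowest in sample 2 at 6.47. Their span was 0.19 without sample 2 and 0.27 without sample 3. DNA replication genes spanned 0.25 (percentile 99.45), with Cdc6 at 6.08 in sample 1 and 7.17 in sample 3, Mcm5 highest in sample 3 at 8.33 and Prim1 highest in sample 1 at 7.65, and the span was 0.11 without sample 3. Hypoxia and glycolysis genes spanned 0.41 with 9 of 14 highest in sample 3, Egln3 and Slc2a1 at 6.96 and 9.65 there, while Adm was lowest there at 4.61, and this span was 0.032 without sample 3 and 0.26 with the mean of the members. Interferon-stimulated genes spanned 0.35 (percentile 99.99) with 12 of 18 highest in sample 2, Cxcl10 at 8.64 against 7.86 and 7.96, while Cxcl9 was lowest there at 7.25 and Bst2 was lowest in sample 3 at 6.72. Without sample 2 this span was 0.050. Chemokines and cytokines spanned 0.35 (percentile 99.99), with Ccl7 and Ccl8 at 7.69 and 7.25 in sample 3 and at 9.36 and 9.77 in sample 1, and Cxcl1 highest in sample 2 at 9.15. Without sample 2 this span was 0.040. Imprinted growth genes spanned 0.51 (percentile 99.99) with 9 of 11 highest in sample 2, Cdkn1c at 7.25 and Ndn at 6.88, and Meg3 lowest in sample 1 at 7.13, and the span was 0.32 without sample 1 and 0.24 without sample 2. Ribosomal protein genes spanned 0.23 (percentile 97.52), with Rpl7, Rplp0 and Rps3 lowest in sample 2 at 10.09, 9.11 and 11.05, and the span was 0.027 without sample 2. It was 0.13 both with quantile normalization and with the mean of a gene's probe sets, and below the 95th percentile in both. Glial genes spanned 0.28 (percentile 95.59), with Pmp22 and Cdh19 highest in sample 2 at 10.40 and 5.24 and Ncam1 highest in sample 3 at 8.65, and the span was 0.074 without sample 1.

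The other 9 lists lay below the 95th percentile. Their spans were 0.033 for oxidative phosphorylation, 0.03 for the microRNA machinery, 0.095 for let-7 targets, 0.098 for p53 targets, 0.11 for genes induced by tissue dissociation, 0.14 for erythroid and platelet genes, 0.16 for epithelial and gland genes, 0.18 for adipocyte genes and 0.19 for the unfolded protein response. Among dissociation-induced genes Fos was at 10.17 ± 0.094, Fosb at 9.94 ± 0.20, Jun at 10.82 ± 0.18 and Junb at 10.96 ± 0.21 (SD, n = 3 each). Among the let-7 targets Hmga2 was at 6.04 ± 0.080 (SD, n = 3). Since no sample was measured on a second array, none of the differences between samples could be set against technical noise.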

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

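The counts of genes and lists kept within 1.5 times their value under most alternatives. Detected genes numbered 7867 with the 99th percentile of the receptor genes as reference, against 12508, and 11735 to 14871 under the others. Lists with a different detected share numbered 12 with protein-coding genes as background, chosen after seeing the data, against 19, and 18 to 21 under the others. Both changes follow from the construction, a stricter level and a background with more detected genes. Genes with a range above the threshold numbered 2717 at 1.5-fold and 77 at 4-fold against 777 at 2-fold, 248 to 471 with 1 sample left out, where fewer values enter each range, and 608 to 825 under the rest. The lists varying between samples numbered 18 to 25, and 17 to 21 of the main 25 recurred with 1 sample left out. The lowest Pearson's r was 0.983 without the filter on dim genes and 0.956 with it.

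The detected share turned from above to below that of other genes, or the reverse, in 14 cases, each with an adjusted p above 0.05 under the alternative. With the 99th percentile as reference the share was 21.4% for T cell, 17.6% for endothelial, 35.7% for adipocyte and 20% for let-7 genes, so the T cell excess of detected members (adjusted p = 0.0235 by Fisher's exact test) became a share below that of other genes (adjusted p = 0.345 by the exact test). With the 90th percentile it was 75% for natural killer and 81.8% for epithelial genes. With the median of all probe sets as background it was 35.3% for endothelial, 50.0% for adipocyte and 40.0% for erythroid genes. With the mean over arrays it was 66.7% for natural killer and for muscle fibre genes. With 1 sample left out it ran from 60% to 66.7% for muscle fibre genes, highest without sample 1, and from 58.3% to 66.7% for natural killer genes, highest without sample 2. It was 64.7% for endothelial genes against protein-coding genes, whose own share was higher. Of 340 detected shares over all lists and alternatives, 326 stayed on their side and 14 turned, while 13 lost and 8 gained a call. With the 99th percentile 18 lists had an excess and 1 a lack, the epithelial and gland genes, at 0% detected (adjusted p = 0.0172 by the exact test). The other gains were in complement, p53 target and Hedgehog genes. The cause of the single turns was not tested.

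No paired analysis was possible because there is 1 group. Probe sets with tied values limit what a small SD shows, and background correction could not be varied.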

Other observations

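Except for quantile normalization, the tests here were chosen after the variation between samples was seen, and the bounds for the lymph node, gland, resident macrophage and monocyte lists were set before the values of those lists were examined. The study's design gives no group within these 3 samples, so no biological difference named by the design was tested.

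Most genes typical of tissue-resident perivascular macrophages were lowest in sample 3, and so were some general macrophage genes. Lyve1, Folr2, Vsig4, Cd163 and Cbr2 were at 7.13, 6.61, 5.54, 6.27 and 7.62 in sample 3, against 9.38, 9.12, 8.22, 8.0 and 9.42 in sample 1 and 9.90, 9.64, 8.86, 8.68 and 9.97 in sample 2. A second list without these genes, among them Timd4 (6.62, 7.51 and 5.64 in samples 1 to 3), Stab1 (8.50, 8.80 and 7.49) and Fcna (7.04, 7.39 and 5.72), had a median of -0.675 in sample 3 relative to the gene means over 14 detected members, with a 95% bootstrap interval over members from -0.816 to -0.486. Mgl2 was an exception, highest in sample 3 at 8.09. Fibroblasts also make Igf1, Gas6 and Selenop, and without these 3 the median was -0.684 over 11 members, interval -0.82 to -0.30. Inflammatory monocyte genes such as Hp (10.51, 10.81 and 11.38) and F10 (7.37, 7.57 and 8.63) had a median of 0.323 in sample 3, interval 0.121 to 0.463, which met the bound set in advance against a lower share of macrophages and monocytes of every kind. That bound was wrong for this list, because neutrophils also express 6 of its members and the neutrophil median in sample 3 was 0.45, interval 0.28 to 0.55. Without these 6, a check added after the result was seen, the median was 0.12, interval -0.05 to 0.51. The 24 macrophage and monocyte genes of the fixed list had a median of -0.08 in sample 3, interval -0.36 to 0.07, with 15 below their mean. Of these 24, 12 were lowest in sample 3: Cd163, Adgre1, Csf1r, Mrc1, Fcgr1, Mertk, C1qa, C1qb, Ms4a7, Trem2, Apoe and Cx3cr1. The 8 highest there were Lyz2, Itgam, Fcgr3, Ccr2, Ly6c2, Tyrobp, Fcer1g and Arg1. Genes shared with neutrophils were not left out of this list, so its median may understate a fall of macrophage genes. Adgre1 (9.46, 9.19 and 8.47 in samples 1 to 3) and Ms4a7 (10.19, 10.01 and 9.18) were lowest there. Itgam (9.66, 9.81 and 10.23) was highest there. A smaller resident macrophage fraction in sample 3 may account for the pattern, as a hypothesis. The interval of the fixed list includes 0 and also values well below it. A lower share of all macrophages therefore stays open, as does lower expression per cell.

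The lower fibroblast, matrix, pericyte and complement genes of sample 3 were weighed against a scaling difference and against a simple dilution. The fibroblast median in sample 3 was -0.469, while random lists of genes of the same intensity lay between -0.085 and 0.087 in 95% of draws. A scaling of that array by intensity would move those genes alike, and with quantile normalization the fibroblast span was 0.92 against 0.89, so both values argue against it. A smaller fibroblast-lineage share alone would raise the genes of other cell types, and of the 15 fixed lists of cell types other than fibroblasts and pericytes 0 were lower in sample 3 than in both other samples by their intervals, while 3, neutrophil, endothelial and myogenic genes, were higher than in both. Against sample 1 alone, T cell genes lay at -0.55 (interval -0.83 to -0.38) and B cell genes at -1.04 (-1.88 to -0.64), and against sample 2 no list was lower by its interval. T and B cell genes below sample 1 would not follow from a smaller share alone. They could also come from sample 1, where both lists were highest. The resident macrophage list was written after Lyve1 and others were seen lowest in sample 3. Without its 3 genes that fibroblasts also make, its medians were 0.12, 0.44 and -0.68 in samples 1 to 3. The interval in sample 3 ran from -0.82 to -0.30. These values argue against a smaller fibroblast-lineage share as the only difference among the 3 samples. They do not decide whether it alone sets sample 3 apart. The bound for that, a fixed list lower than in both other samples beside others that were higher, was not met. Such a share beside other differences stays open, as do dissection and sorting.

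The T and B cell genes of sample 1 were weighed against blood, lymph node tissue and the sex of the animal. The neutrophil median in sample 1 was -0.404, interval -0.497 to -0.249, but these genes were high in all 3 samples and could hide a small share of blood. Erythroid and platelet genes had a median of 0.098 in sample 1, interval -0.58 to 0.39, over the 5 measured of 11 members. These were Slc4a1, of red cells, and the platelet genes Pf4, Ppbp, Itga2b and Gp9. Of the 5, 2 were highest in sample 1 and 2 lowest, among the latter Slc4a1 at 8.47 against 8.94 and 8.65. So few members decide little, and blood stays open. Lymph node stromal genes had a median of -0.039, interval -0.132 to 0.072, over 8 detected members, so lymph node tissue could be neither shown nor excluded, and the sort would remove its endothelial part. Lymphocyte genes written as naive and recirculating had a median of 0.43 in sample 1 over 7 members. Sex cannot be told apart from the sample, since Xist was above the background reference on 1 array and the Y-linked genes on the other 2.

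Gland genes differed by sample. Dcpp1, Dcpp2 and Dcpp3, secreted proteins of salivary glands, were at 8.45, 8.91 and 7.81 in sample 1, 11.17, 11.36 and 11.45 in sample 2, and 10.50, 10.81 and 11.03 in sample 3, and the sort would not remove gland cells. These near-identical copies may share signal, which was not tested. Lipf and Bpifb1 were high in sample 2 alone, at 9.24 and 9.36, so an average over samples 2 and 3 does not match their pattern. For other gland genes, the mean of samples 2 and 3 lay 0.149 above sample 1, interval -0.056 to 0.309. Taken singly, sample 2 lay at -0.16 against sample 1 (interval -0.29 to 0.21) and sample 3 at 0.23 (0.05 to 0.55), and the list medians were -0.10, -0.22 and 0.22 for samples 1 to 3. That interval met the bound of 0.5 set in advance for excluding gland cells carried into samples 2 and 3. After this result was seen, a condition that 80% of the measured members be detected was added, which makes the test undecided. The reason is that only 13 of 21 members were detected and that they moved apart, with Bpifa2 highest in sample 2 (5.43 against 3.88 and 3.94) and Muc5b and Bpifb2 highest in sample 3 (10.01 and 9.45) and lowest in sample 2 (8.86 and 8.22, against 9.12 and 8.34 in sample 1), so a median over them decides little.

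Tg, which encodes the thyroid hormone precursor, was at 7.72 and 7.92 in samples 1 and 2 and at 5.20 in sample 3. A list of 5 other detected thyroid genes had a range of 0.071 between samples, at percentile 19.4 of random lists. Only these 5 of 9 measured members were detected on at least 1 array. Foxe1 (5.44, 5.46 and 5.13 in samples 1 to 3) and Iyd (5.23, 4.76 and 4.76) lay near the background reference. The list therefore cannot decide whether thyroid tissue accounts for Tg.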
